A study of Mus musculus with 56 samples.

How the data were processed

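The data are signal values of 56 expression arrays of mouse gastrocnemius RNA. As deposited, each value is an intensity for 1 probe set on a linear scale, made by the authors, and how the probes were summarised and normalised is not given in the sources used here. The table held 45037 probe sets. Values ran from -20 to 15890, 0.46% of them lay below 0, and array medians ran from 62.5 to 77.5. There is no read depth for arrays, and probe sets near background limit which genes can be seen. RNA amplification and labelling by the authors, as the labels give them, were the same for all arrays.

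Values were floored at -15, which moved 5 of 2522072, 16 was added, and log2 was taken. No further scaling was applied, and the shift of array medians was checked with quantile normalization as an alternative. Probe sets were joined to gene symbols with the platform annotation, and symbols were read from a RefSeq table for assembly GRCm38.p6, of which only gene names were used. Of the probe sets 34945 had 1 gene symbol, 932 had several and were left out, and 9160 had none and were left out. For each of the 18193 genes the probe set of highest mean was kept, and genes below the 40th percentile of all probe sets, a log2 level of 5.71, were left out, which left 12351. Of these, 565 are measured by probe sets whose suffix marks shared sequence, and these were not named in the text. Y-linked genes, 9 probe sets, all lay below the filter in these female mice. Myostatin had no usable probe set with 1 symbol and was not analysed here.

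Groups were taken from the labels before the data were examined, as were the comparisons, the thresholds, the rule for named genes and most alternatives. The gene lists were fixed then too, except those of lymph node, lung, liver and further dioxin receptor target genes. The 2 arrays of mouse G8 were averaged, which gave 55 mice in 9 groups. A single limma model held all groups, with 46 residual degrees of freedom and 48.2 after moderation, and 14 comparisons were taken from it. The model takes each gene's spread as equal in all groups. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p values of genes in the text are from these moderated t tests. Genes named for each comparison were those of largest change among those past the threshold (up to 8 each way for exposure comparisons, 5 for others), or the 5 of lowest p where none passed. Members of lowest p in the lists that passed and 15 genes fixed beforehand, of which 14 were measured, were also named.

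Of 38 gene lists, 34 had at least 5 measured genes and were tested with camera at a preset correlation between genes of 0.01, with adjustment over lists. Camera with the correlation estimated from the data, and fry, were run as alternatives. For each list the genes past the threshold over all genes, and those past when the adjustment ran over the list alone, were counted. The score of the 12-week response used 100 genes, since fewer than 20 genes passed, and was compared by exact permutation of mice between groups. Each comparison was also run on 100 groupings of the same mice, the true one among them and the others mixed. Samples far from their group were found with Dixon's ratio of gap to range.

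Alternatives were another filter or none, all probe sets, the mean of probe sets, other pseudocounts (1 and 64) and quantile normalization. Others were robust moderation with a trend, array weights, a fit of the compared groups alone, the G8 arrays kept apart or reduced to 1, arrays outside the main run of sample identifiers left out, the number in the sample titles as a covariate, an adjusted p under 0.1, and each replicate left out in turn. After the data were seen, fits were added without the 12 lymph node arrays, with the lymphocyte mean as a covariate, and without the outlying array of 24 weeks of smoke.

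The model was tested on simulated data with the real means and spreads of 12351 genes. Of 100 genes changed by 1 on the log2 scale it found 92, 94 and 90 at 2, 12 and 24 weeks of smoke and 91 in cessation RA against air, and of 100 changed by 0.5 it found 61, 61, 63 and 54, with 12, 10, 9 and 11 false calls. In the simulation genes were drawn independently, with equal spread in all groups. Shifts shared by many genes, as in the lymph node arrays, were absent, so false calls in the real data can differ. R 4.3.3, limma 3.58.1, the data.table package (1.17.8), Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.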

Results

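RNA of the gastrocnemius, the large calf muscle, of female C57BL/6 mice was measured on 56 expression arrays. Mice had breathed mainstream cigarette smoke or air through the nose, the air being the sham exposure, for 2, 12 or 24 weeks. Cessation mice had 12 weeks of smoke and then 12 weeks without it, in an arm named FA and an arm named RA, abbreviations that the sources used here do not define. Labels of the sham air groups also carry FA and none carries RA, so whether RA mice breathed the same kind of air is not known. The 9 groups were untreated mice at week 0, sham air and smoke at 2, 12 and 24 weeks, and both cessation arms. Each group had 6 arrays from 6 mice, except smoke at 12 weeks, with 8 arrays from 7 mice. The 2 arrays of 1 of these mice were averaged, which left 55 mice. Array medians of the deposited intensity ran from 62.5 to 77.5, and the number of arrays limits the precision. All levels are log2 of the intensity plus 16, errors of levels are SDs between mice, errors of differences are SEs, and 12351 genes were tested.

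Lymphocyte genes set 12 arrays apart from the other 44. The mean of the 12 measured lymphocyte marker genes, which include the B cell gene Ms4a1 and the T cell genes Cd3e and Cd8a, lay between 9.60 and 12.24 in these 12 arrays and at most at 7.54 in the others. Glycam1, a gene of lymph node vessels and of milk glands, was 13.37 in untreated replicate 1, which is 1 of the 12, and 7.02 in untreated replicate 2, which is not. The arrays came from 1 of 6 untreated mice, 1 of 6 mice after 2 weeks of sham air, 2 of 7 after 12 weeks of smoke and 1 of 6 after 24 weeks of sham air. They also came from 3 of 6 mice after 24 weeks of smoke, 1 of 6 in cessation FA and 3 of 6 in cessation RA. Mouse G8 of the 12-week smoke group had 1 array of each kind, with lymphocyte means of 5.39 and 10.93. The first principal component held 58.7% of the variance and its r with the lymphocyte mean across arrays was 0.98 in size, over arrays that fall into separate clusters, so that this value only restates the split. A single array, replicate 6 of 24 weeks of smoke, stood further apart. Its mean r with the other arrays across genes was 0.826, its lymphocyte mean 12.24 and its mean over cell cycle genes 10.23.

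**Figure D1:**
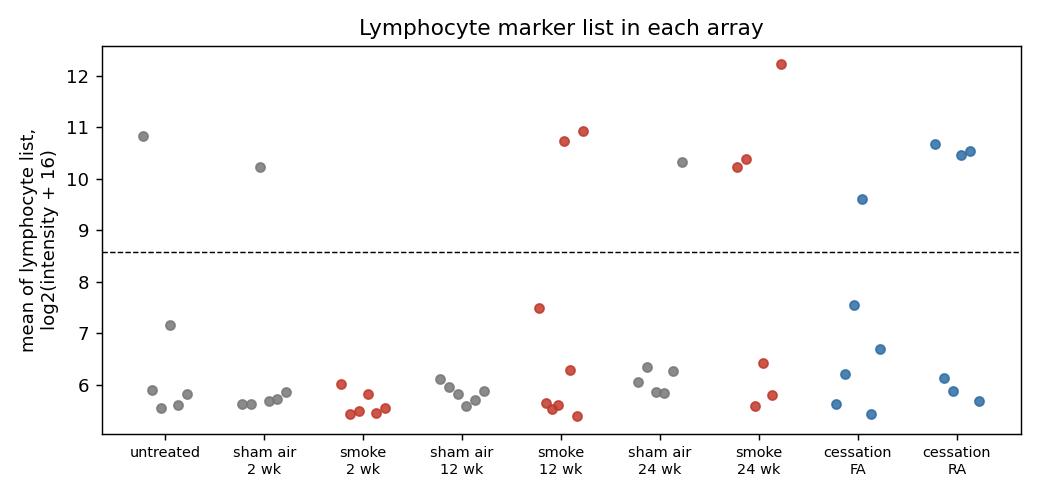
Mean of the lymphocyte marker list in each array, as log2 of intensity plus 16, by group, with unsmoked groups in grey, smoke groups in red and cessation groups in blue. The dashed line at 8.57 parts the 12 arrays at 9.60 or more from the 44 arrays at 7.54 or less.

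Smoke for 2 weeks was compared with sham air of the same length to find early changes in muscle. No gene passed. Among the 5 genes of lowest p was Pdk4, the kinase that switches off pyruvate dehydrogenase, at 12.78 ± 0.15 (SD, n = 6) with smoke and 12.29 ± 0.36 (n = 6) with air. Another was Kcng4, a potassium channel subunit, at 8.54 ± 0.21 and 7.83 ± 0.24 (n = 6 each). Of the 30 measured genes of fatty acid oxidation and its PPAR regulators 25 were above 0, with 1 gene higher when adjusted over the list alone and none over all genes. Camera placed the list higher (adjusted p = 0.00056; adjusted p = 0.71 with an estimated correlation). Its member Ucp3, a mitochondrial uncoupling protein of muscle, differed by 0.72 ± 0.27 (SE, n = 6 each) and did not pass. Lipogenesis and sterol synthesis genes had 1 of 22 measured members above 0 and a median of -0.25, with none past over all genes or adjusted over the list alone. Camera placed them lower (adjusted p = 2.8e-06; adjusted p = 0.71 with an estimated correlation). Without the lymph node arrays, 1 of 6 in air and none of 6 in smoke, their median was -0.15. Scd2, a fatty acid desaturase, differed by -0.48 ± 0.21 (SE) and Srebf1, the transcription factor of lipogenesis, by -0.38 ± 0.19, and these were -0.36 and -0.22 without those arrays. Adipocyte markers had 3 of 13 members above 0, a median of -0.57 that did not pass (adjusted p = 0.057; adjusted p = 0.83 with an estimated correlation) and -0.15 without those arrays. The count of 0 is from limma, with 255 genes at an unadjusted p under 0.05 where chance gives 618 on average. Genes that shift together let such a number lie far from 618, so 255 does not show that smoke had no effect. No other tool was run gene by gene. When every probe set was tested, 1 passed.

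Smoke for 12 weeks, the exposure that the cessation mice also had, was compared with 12 weeks of sham air. Cyp1a1, the cytochrome P450 that the dioxin receptor AHR switches on and that breaks down smoke hydrocarbons (Entrez 13076), was 8.74 ± 0.64 (SD, n = 7) with smoke and 7.27 ± 0.13 (n = 6) with air. It rose 2.78-fold, by 1.47 ± 0.24 (SE) on the log2 scale (adjusted p = 0.0017), and 7 of 7 smoke mice lay above the highest air mouse (two-sided exact permutation p = 0.0012). It was the only gene of 12351 to pass, as 1 of the 7 measured genes of the AHR battery, and 1 also when adjusted over the list alone. Camera placed the battery higher (median 0.04, mean 0.43, adjusted p = 0.0021; adjusted p = 0.18 with an estimated correlation). Cyp1b1, a second P450 of the battery, differed by 1.41 ± 0.73 and Nqo1, a quinone reductase, by -0.12 ± 0.16 (SE), and neither passed. They were at 0.59 and 0.03 without the lymph node arrays, where the battery's median stayed at 0.04. Lymphocyte markers had a median difference of 1.22 (adjusted p = 6.5e-05; adjusted p = 0.85 with an estimated correlation), and none of 12 members passed. Of the mice, 2 of 7 with smoke and none of 6 with air had an array with lymph node genes, and without these arrays the median was 0.15. Adipocyte markers such as Adipoq, the fat hormone adiponectin, at 11.53 ± 0.78 (n = 7) and 10.84 ± 0.40 (n = 6), had a median of 0.58 and none past (adjusted p = 6.5e-05; adjusted p = 0.85 with an estimated correlation). Their median was 0.17 without the lymph node arrays. Over 17 alternatives of the processing the Cyp1a1 difference ran from 1.25 to 1.57 and its adjusted p from 0.00018 to 0.51. The call was lost only with the 12-week groups fitted alone, where limma called 0 genes, and 230 genes had an unadjusted p under 0.05 with all groups in the fit.

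Cyp1a1 in the other smoke groups was 7.50 ± 0.23 (SD, n = 6) at 2 weeks against 7.03 ± 0.36 (n = 6) in air, and 7.80 ± 0.77 (n = 6) at 24 weeks against 7.43 ± 0.33 (n = 6) in air. The exact permutation p of these differences, two-sided and unadjusted over the 3 times, was 0.026 at 2 weeks, with 4 of 6 smoke mice above the highest air mouse, and 0.31 at 24 weeks, with 3 of 6. In limma neither passed, with adjusted p = 1 at 2 weeks and adjusted p = 0.33 at 24 weeks. At 24 weeks smoke replicate 6 was at 6.43. The difference there was 0.64 without it (exact p = 0.015, adjusted p = 0.29) and 0.60 without the lymph node arrays (exact p = 0.089, adjusted p = 0.22), against 0.37 with all mice. After cessation it was 7.47 ± 0.34 (n = 6) in FA and 7.35 ± 0.33 (n = 6) in RA. These differed from 24 weeks of air by 0.04 ± 0.25 and -0.09 ± 0.25 (SE).

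**Figure D2:**
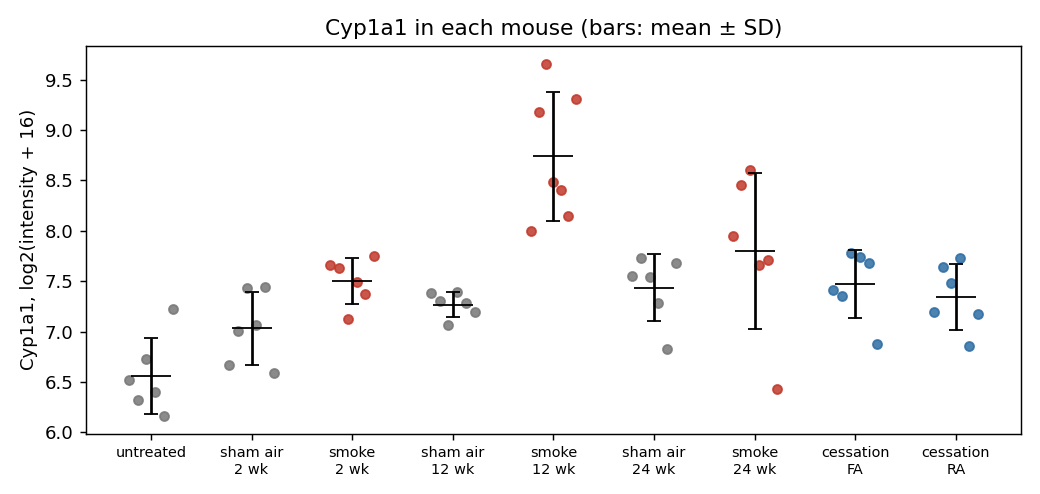
Cyp1a1 in each mouse, as log2 of intensity plus 16, by group, with bars for mean ± SD. The 7 mice after 12 weeks of smoke lie between 8.00 and 9.66 and the 6 after 12 weeks of sham air between 7.06 and 7.39.

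Smoke for 24 weeks was compared with 24 weeks of sham air, and 58 genes passed, 7 higher and 51 lower. Nr1d1, the nuclear receptor REV-ERB alpha that represses clock genes (Entrez 217166), was 8.77 ± 0.58 with smoke and 9.90 ± 0.20 with air (SD, n = 6 each), 2.19-fold lower (adjusted p = 4.6e-05). It was lower in 6 of 6 smoke mice than in any air mouse. Smox, spermine oxidase of polyamine breakdown, fell by 1.03 ± 0.18 (SE, adjusted p = 0.0019), also in 6 of 6 mice. Casr, the calcium-sensing receptor, differed by -0.91 ± 0.19, Alox12, a lipoxygenase, by -0.96 ± 0.22, Ntsr2, a neurotensin receptor, by -0.88 ± 0.22 and Kcnf1, a potassium channel subunit, by -0.88 ± 0.22, and each fell with an adjusted p from 0.019 to 0.047. The transcripts 1110046J04Rik and D630024D03Rik fell, by 1.00 ± 0.20 and 0.97 ± 0.23. Among genes that rose, Pus7l, a pseudouridine synthase relative, gained 0.44 ± 0.10, Ell2, a transcription elongation factor, 0.43 ± 0.09, Nufip2, an RNA-binding protein, 0.31 ± 0.07 and Cep97, a centrosome protein, 0.26 ± 0.05 (adjusted p 0.019 to 0.03). The gene 1810030O07Rik and the ubiquitin-like Tmub2 rose by 0.23 ± 0.06 and 0.21 ± 0.05. Without smoke replicate 6 the count was 4, and all 4 had been among the 58: Nr1d1 at -0.90, Smox at -0.83, and 2 that were chosen after their values were seen, Dusp10, a phosphatase of stress kinases, at -0.69 and Glt28d2 at -0.58. Without the lymph node arrays 45 genes passed on 3 and 5 mice, 15 of them among the 58. Nr1d1 (-1.06), D630024D03Rik (-0.96), Cep97 (0.28) and 1810030O07Rik (0.31) then still passed. Smox (-0.68), Casr (-0.57), Ntsr2 (-0.68), Kcnf1 (-0.40), Alox12 (-1.05) and 1110046J04Rik (-0.86) no longer did, nor did Pus7l, Ell2, Nufip2 and Tmub2 (0.41, 0.40, 0.25 and 0.24). The count was also 529, 474, 547 and 471 without smoke replicates 1, 2, 3 and 4, and 12, 285, 16, 35 and 34 without air replicates 1, 3, 4, 5 and 6. In a fit of both groups alone limma called 0, beside 3044 genes at an unadjusted p under 0.05 in the fit of all groups. Over 17 alternatives Nr1d1 ran from -1.16 to -1.04, with an adjusted p from 1.4e-06 to 0.46, past in 16. Ell2 ran from 0.02 to 0.45 and was past in 12.

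Gene groups at 24 weeks were read beside lymph node arrays in 3 of 6 smoke mice and 1 of 6 air mice. Of 20 measured clock and clock-output genes 2 fell, Nr1d1 and Dbp, and 11 fell when adjusted over the list alone (camera adjusted p = 5.6e-05; adjusted p = 0.70 with an estimated correlation; fry adjusted p = 0.012). Dbp, a clock-driven transcription factor, was 10.96 ± 0.29 with smoke and 11.66 ± 0.22 with air (SD, n = 6 each), and it no longer passed without the lymph node arrays (-0.48) or without replicate 6 (-0.59). The clock list had a median of -0.23, which was -0.08 without the lymph node arrays and -0.10 without replicate 6. Fatty acid oxidation genes had 10 of 30 lower over the list alone and none over all genes, with a median of -0.22 (adjusted p = 0.0011; adjusted p = 0.70 with an estimated correlation), -0.15 without the lymph node arrays and -0.06 without replicate 6. Slow fibre genes, which set apart oxidative muscle fibres, had a median of -0.44 in 16 genes, none past (adjusted p = 0.0017; adjusted p = 0.70 with an estimated correlation), -0.41 without the lymph node arrays and -0.21 without replicate 6. Of 70 genes of oxidative phosphorylation 11 were above 0 and none passed, with a median of -0.08 (adjusted p = 4.1e-05; adjusted p = 0.70 with an estimated correlation). Of 19 endothelial markers 1 fell, 6 over the list alone, with a median of -0.20 (adjusted p = 0.0021; adjusted p = 0.70 with an estimated correlation), -0.18 without the lymph node arrays and -0.03 without replicate 6. Cell cycle genes had a median of 0.72, with 4 of 19 higher over the list alone and none over all genes (adjusted p = 7.1e-07; adjusted p = 0.70 with an estimated correlation). Their median was -0.02 without the lymph node arrays and 0.29 without replicate 6. Unfolded protein response genes had a median of 0.28 in 25 genes, none past (adjusted p = 0.00025; adjusted p = 0.70 with an estimated correlation), -0.08 without those arrays and 0.03 without replicate 6. Trim63 and Fbxo32, the ubiquitin ligases of muscle atrophy, differed by -0.27 ± 0.15 and -0.30 ± 0.22 (SE), and neither passed. They were at 0.06 and -0.23 without the lymph node arrays and at -0.04 and -0.12 without replicate 6.

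Averaged over the 3 times, smoke differed from sham air in 4 genes, 1 higher and 3 lower. Cyp1a1 rose by 0.77 ± 0.14 (SE, n = 19 smoke and 18 air mice, adjusted p = 0.0064), with 11 of 19 smoke mice above the highest air mouse and 1 below the lowest. Nr1d1 fell by 0.53 ± 0.09 (adjusted p = 0.0026), Dusp10 by 0.43 ± 0.07 (adjusted p = 0.0026) and 1110046J04Rik by 0.61 ± 0.11 (adjusted p = 0.0064). By time, Nr1d1 differed by -0.06, -0.39 and -1.13 at 2, 12 and 24 weeks. Dusp10 was 11.12, 11.16 and 10.37 with smoke at these times and 11.33, 11.41 and 11.21 in air. The averages of Nr1d1 and Dusp10 thus hold unequal differences, largest at 24 weeks. Of 19 endothelial markers none was above 0 and none passed over all genes, with 2 lower over the list alone (median -0.11, adjusted p = 0.00066; adjusted p = 0.90 with an estimated correlation). Flt1, a receptor for the vessel growth factor VEGF, differed by -0.21 ± 0.08 and Tie1, a vessel receptor kinase, by -0.21 ± 0.06 (SE), and Flt1 by -0.13 without the lymph node arrays. There the endothelial median was -0.10 (adjusted p = 0.0013; adjusted p = 0.33 with an estimated correlation), and 19 genes passed, all 4 named here among them. The count was 10 without 12-week smoke replicate 1, and 7 and 9 without 24-week smoke replicates 1 and 2.

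Cessation was compared with 24 weeks of sham air to see what was left of smoke after 12 weeks without it, first in the FA arm. Arntl, the clock transcription factor BMAL1 (Entrez 11865), rose by 0.73 ± 0.16 (SE, n = 6 each, adjusted p = 0.039), from 8.70 ± 0.35 to 9.43 ± 0.16 (SD), with 6 of 6 cessation mice above any air mouse. It was the only one of 10 genes to rise. Noct, a rhythmic clock-output gene, fell by 0.49 ± 0.11 and Wee1, a kinase that holds back cell division and is driven by the clock, fell by 0.48 ± 0.10. Tinagl1, a matrix protein, fell by 0.61 ± 0.13, and Mid1ip1, a regulator of lipogenesis, by 0.61 ± 0.13. Bcl2l1, an inhibitor of cell death, fell by 0.41 ± 0.08 and Nrip1, a co-repressor of nuclear receptors, by 0.38 ± 0.08. Rapgef3, which relays cyclic AMP, and Fam193b fell by 0.44 ± 0.10 and 0.36 ± 0.08. All of these had an adjusted p of 0.034 or 0.039. Of 20 clock genes 1 rose and 1 fell over all genes, and 3 rose and 7 fell when adjusted over the list alone (camera adjusted p = 0.01; adjusted p = 0.94 with an estimated correlation). Glucocorticoid response genes, which respond to the stress hormone, had 2 of 18 lower over the list alone, none over all genes, and a median of -0.11 (adjusted p = 0.0012; adjusted p = 0.94 with an estimated correlation). Interferon response genes had 19 of 23 above 0, none past, and a median of 0.27 (adjusted p = 0.0012; adjusted p = 0.94 with an estimated correlation). With the lymph node arrays left out 29 genes passed, all 10 among them. The count of 10 was 0 without air replicate 2, 5 or 6, 0 without cessation FA replicate 2 or 6, and 1, 6 and 5 without FA replicates 1, 4 and 5. It was 0 with no filter on dim genes and in a fit of both groups alone. Over 17 alternatives the Arntl difference ran from 0.40 to 0.75 with an adjusted p from 0.012 to 0.29, past in 13.

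Cessation in the RA arm differed from 24 weeks of sham air in 217 genes, 75 higher and 142 lower. Npas2, a partner of BMAL1 (Entrez 18143), was 8.18 ± 0.49 after cessation and 6.38 ± 0.25 in air (SD, n = 6 each), 3.49-fold higher (adjusted p = 4.7e-08). Arntl rose by 1.20 ± 0.16 (SE, adjusted p = 1.9e-06). Per1 and Per2 (Entrez 18626 and 18627), the period genes that shut off the clock's activators, fell by 1.93 ± 0.22 (adjusted p = 4.7e-08) and 1.58 ± 0.20 (adjusted p = 1e-06), and Ciart, a clock repressor, by 1.41 ± 0.24. Each of these 5 separated 6 of 6 cessation mice from every air mouse, and Dbp fell by 0.48 ± 0.14 (adjusted p = 0.048). Of 20 measured clock genes 4 rose and 9 fell, and 4 rose and 10 fell when adjusted over the list alone (camera adjusted p = 0.00011; adjusted p = 0.78 with an estimated correlation; fry adjusted p = 0.032). Glucocorticoid response genes fell in 4 of 18 cases, and in 10 when adjusted over the list alone (camera adjusted p = 6.8e-06; adjusted p = 0.38 with an estimated correlation; fry adjusted p = 0.0096). These were led by Arrdc2, an arrestin relative, 6.50-fold lower at 7.88 ± 0.40 against 10.58 ± 0.74 (SD). The others were Gadd45g, a growth arrest gene, at -1.38 ± 0.31, Tsc22d3, the glucocorticoid-induced leucine zipper, at -0.54 ± 0.09, and Mt2, a metallothionein, at -0.92 ± 0.25 (SE).

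**Figure D3:**
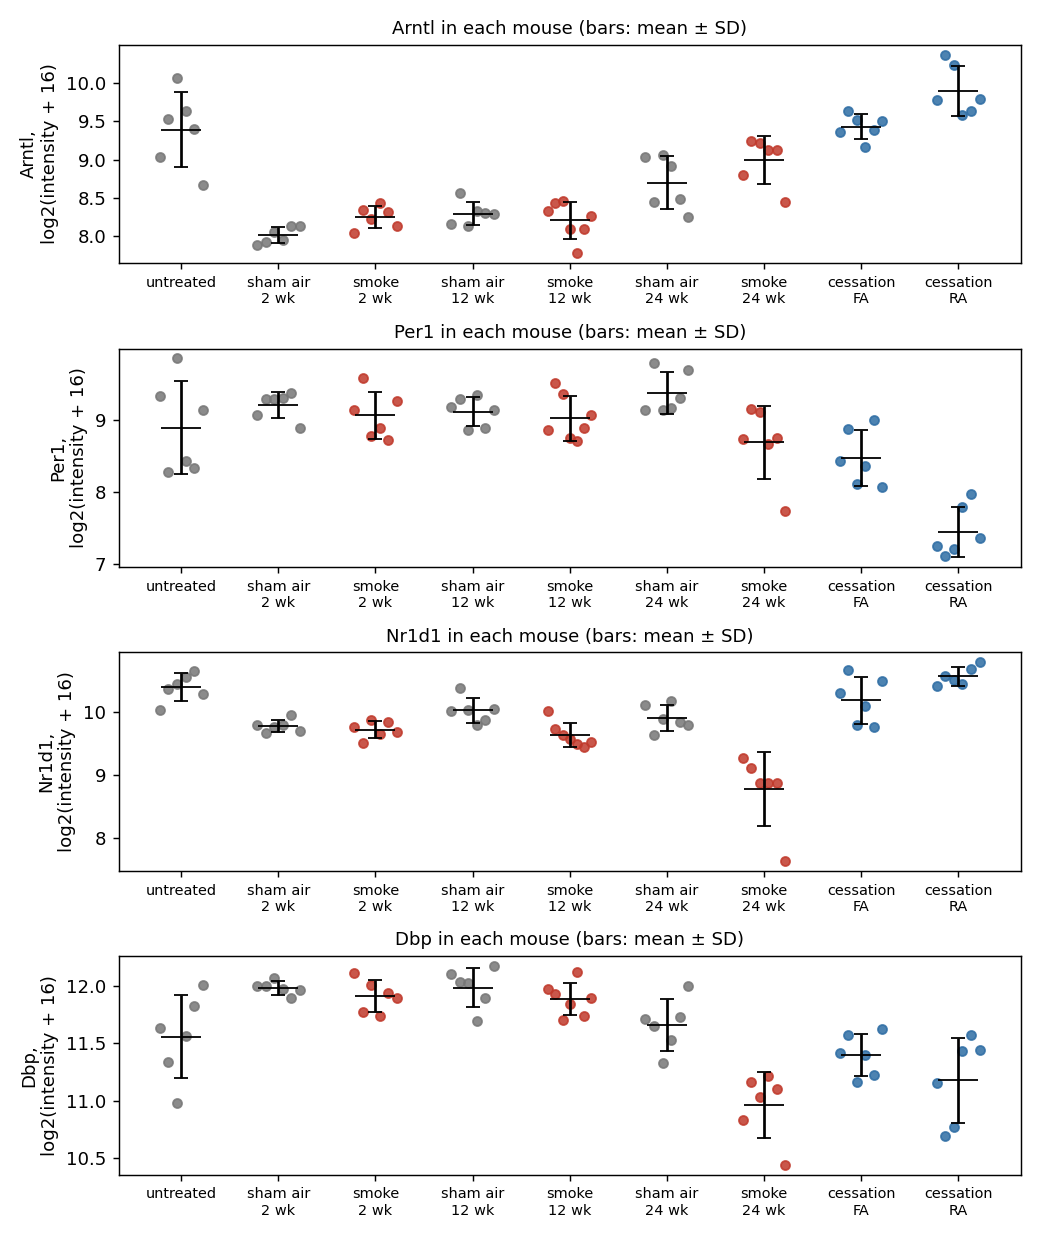
Clock genes in each mouse, as log2 of intensity plus 16, by group, with bars for mean ± SD. Per1 averaged 7.44 in cessation RA and 9.37 after 24 weeks of sham air, and Arntl averaged 9.39 in untreated mice and 8.01 after 2 weeks of sham air.

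Outside the clock, genes that rose in cessation RA included Aplnr, the apelin receptor of vessels, by 1.14 ± 0.19 (SE, n = 6 each, adjusted p = 0.00022). Sox4, a transcription factor, rose by 1.09 ± 0.22 and Adamts4, a protease of cartilage matrix, by 0.99 ± 0.20, both with an adjusted p of 0.002. Prss55, a serine protease, gained 1.16 ± 0.21, Tpx2, a spindle protein, 0.79 ± 0.19 and Gpr34, a receptor of immune cells, 1.24 ± 0.34. Genes that fell included Nmb, the peptide neuromedin B, at -1.36 ± 0.21 (adjusted p = 4.6e-05), Nr4a2, an orphan nuclear receptor, at -1.28 ± 0.33 and Slc18a1, a vesicle transporter of monoamines, at -1.22 ± 0.29. Of 33 extracellular matrix genes 1 fell over all genes, Timp3, an inhibitor of matrix proteases, by 0.42 ± 0.08 (adjusted p = 0.0024). When adjusted over the list alone 3 rose and 1 fell (median 0.09, adjusted p = 0.0088; adjusted p = 0.99 with an estimated correlation). Lymphocyte markers had a median of 1.44 (adjusted p = 0.0044; adjusted p = 0.99 with an estimated correlation), with lymph node arrays in 3 of 6 cessation RA mice and 1 of 6 air mice. Without those arrays 490 genes passed on 3 and 5 mice, 151 of them among the 217, the matrix median was -0.01, and Per1, Npas2 and Arrdc2 differed by -2.08, 2.03 and -2.59. Mt2 no longer passed (-1.02). The count was 129 and 139 without air replicates 1 and 6 and 130 without cessation RA replicate 1; it was 48 higher and 88 lower without air replicate 2, 39 and 85 without RA replicate 2, and 48 and 85 without RA replicate 3.

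Smoke for 24 weeks was also compared with each cessation arm, which had the same age and 12 weeks less of smoke. Against FA, 438 genes passed, 197 higher and 241 lower. Nr1d1 was 8.77 ± 0.58 with smoke and 10.18 ± 0.37 in FA (SD, n = 6 each), 2.65-fold lower (adjusted p = 9.8e-08). Dusp10 was 10.37 ± 0.41 and 11.47 ± 0.11, 2.14-fold lower (adjusted p = 2.6e-07), and both separated 6 of 6 smoke mice from every FA mouse. Fgf6, a growth factor of muscle, fell by 1.42 ± 0.28 (SE) and Stc2, the hormone stanniocalcin, by 0.98 ± 0.18. Slc20a1, a phosphate transporter, rose by 0.88 ± 0.16, Noxred1 by 0.94 ± 0.14 and Ager, a receptor for glycated proteins, by 1.21 ± 0.31. Of 25 unfolded protein response genes 1 rose, Xbp1, the transcription factor of that response, by 0.52 ± 0.15, and 15 rose when adjusted over the list alone (median 0.44, adjusted p = 2.2e-06; adjusted p = 0.74 with an estimated correlation). Their median was 0.09 without the lymph node arrays and 0.14 without smoke replicate 6. Slow fibre genes had 13 of 16 lower over the list alone, none over all genes, and a median of -0.51 (adjusted p = 0.00021; adjusted p = 0.74 with an estimated correlation), -0.43 without the lymph node arrays and -0.32 without replicate 6. Of 19 cell cycle genes Mcm3, a replication helicase subunit, rose by 0.70 ± 0.21 and Aurka, a mitotic kinase, fell by 0.53 ± 0.15; over the list alone 5 rose and 1 fell (median 0.66, adjusted p = 0.00018; adjusted p = 0.74 with an estimated correlation). The cell cycle median was -0.12 without the lymph node arrays and 0.16 without replicate 6. Without smoke replicate 6 the count was 126 and Nr1d1 differed by -1.18. It was 1360, 1625 and 1322 without smoke replicates 3, 4 and 5, 192, 153, 250 and 193 without FA replicates 1, 2, 3 and 6, and 6 in a fit of both groups alone. Without the lymph node arrays, 3 of 6 in smoke and 1 of 6 in FA, 234 genes passed, 114 of them among the 438, and Fgf6 (-0.64), Ager (1.06), Xbp1 (0.21), Mcm3 (0.30) and Aurka (-0.46) no longer passed. Without smoke replicate 6, Ager (1.21), Xbp1 (0.24), Mcm3 (0.36) and Aurka (-0.53) did not pass either.

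Against RA, 289 genes passed, 116 higher and 173 lower. Per2 was 9.55 ± 0.60 with smoke and 7.93 ± 0.36 in RA (SD, n = 6 each), 3.07-fold higher (adjusted p = 4.4e-07). Per1 was higher with smoke by 1.24 ± 0.22 and Wee1 by 1.02 ± 0.10 (SE). Nr1d1 was 3.46-fold lower (adjusted p = 3.5e-11) with Npas2 at -1.76 ± 0.20. Against 24 weeks of sham air, Per2, Per1 and Npas2 differed by 0.04, -0.68 and 0.04 with smoke. In RA they differed from that air by -1.58, -1.93 and 1.8. Nr1d1 differed from air by -1.13 with smoke and by 0.66 in RA. Wee1 was 9.35 with smoke, 9.23 in air and 8.32 in RA. Differences from RA thus include those of RA from air. Arrdc2 was higher with smoke by 1.91 ± 0.39 and Myog, the myogenic factor myogenin, by 1.23 ± 0.27. Ucp3 was higher by 0.99 ± 0.27 and Mid1, a ubiquitin ligase, by 1.49 ± 0.33, while Cish, a brake on cytokine signals, was lower by 2.21 ± 0.52. Arrdc2 was itself lower in RA than in air, as given above. Of 20 muscle atrophy genes 1 rose and 2 fell, and 1 rose and 6 fell when adjusted over the list alone (median -0.21, adjusted p = 0.015; adjusted p = 0.70 with an estimated correlation), with a median of -0.01 without the lymph node arrays. Endothelial markers fell in 3 of 19 cases, and in 4 over the list alone (median -0.16, adjusted p = 0.0024; adjusted p = 0.70 with an estimated correlation), with a median of -0.04 without replicate 6. Fatty acid oxidation genes had 1 of 30 higher over all genes, Ucp3, and 1 higher and 6 lower over the list alone (median -0.18, adjusted p = 0.00013; adjusted p = 0.70 with an estimated correlation), with a median of -0.06 without replicate 6. The count was 475 and 481 without smoke replicates 3 and 4, 155 and 142 without RA replicates 2 and 3, and 4 in a fit of both groups alone. Both groups had lymph node arrays in 3 of 6 mice, and without them 405 genes passed, 154 of them among the 289. Mid1 (1.19), Ucp3 (1.00) and Cish (-1.96) then no longer passed.

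Between the cessation arms 3 genes passed. Npas2 was 8.18 ± 0.49 in RA and 6.99 ± 0.14 in FA (SD, n = 6 each), 2.30-fold higher (adjusted p = 0.0023). Crip3, a LIM domain protein, rose by 1.43 ± 0.27 (SE, adjusted p = 0.013), and Hdac9, a histone deacetylase of muscle, fell by 0.82 ± 0.12 (adjusted p = 0.00019). Each separated 6 of 6 mice from all mice of the other arm. Without the lymph node arrays, 3 of 6 in RA and 1 of 6 in FA, 4 genes passed, 2 of the 3 among them, and Crip3 no longer did (1.12, adjusted p = 0.24). Of 20 clock genes 1 rose, and 3 rose and 6 fell when adjusted over the list alone (median -0.14, adjusted p = 0.0069; adjusted p = 0.86 with an estimated correlation). Interferon response genes had 4 of 23 above 0, none past, and a median of -0.24 (adjusted p = 0.0043; adjusted p = 0.86 with an estimated correlation), and -0.57 without the lymph node arrays.

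Groups that never met smoke also differed. After 2 weeks of sham air 64 genes differed from untreated mice, 38 higher and 26 lower. Arntl was 8.01 ± 0.11 in air and 9.39 ± 0.49 in untreated mice (SD, n = 6 each), 2.60-fold lower (adjusted p = 2.2e-07), Npas2 fell by 1.48 ± 0.20 (SE) and Per2 rose by 1.22 ± 0.20. Plin5, a coat protein of lipid droplets, fell by 1.49 ± 0.32, Slc25a34, a mitochondrial carrier, by 1.87 ± 0.41 and Fbxo32 by 1.05 ± 0.22, while Clca4a rose by 2.48 ± 0.39 and Nmb by 1.09 ± 0.21. The transcript 1110046J04Rik, lower with smoke on average, rose here without smoke, by 1.26 to 1.69 over 17 alternatives, and passed in all 17. Of 30 fatty acid oxidation genes 2 fell, and 7 when adjusted over the list alone (median -0.17, adjusted p = 1.9e-16; adjusted p = 0.17 with an estimated correlation). Of 22 lipogenesis and sterol genes 1 rose, and 6 over the list alone (median 0.25, adjusted p = 2.9e-06; adjusted p = 0.73 with an estimated correlation). Of 20 muscle atrophy genes 2 fell, also over the list alone (adjusted p = 2.7e-06; adjusted p = 0.14 with an estimated correlation). The count was 35 and 38 without untreated replicates 3 and 4, and 42 and 38 without air replicates 2 and 4; without the lymph node arrays it was 236, with 63 of the 64 among them.

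From 2 to 24 weeks of sham air 27 genes changed, 19 higher and 8 lower. Pdk4 was 12.97 ± 0.19 at 24 weeks and 12.29 ± 0.36 at 2 weeks (SD, n = 6 each), 1.60-fold higher (adjusted p = 0.018), Arntl rose by 0.69 ± 0.16 (SE) and Amy1, an amylase, by 0.78 ± 0.15. Col1a1, a chain of the main fibrous collagen, fell by 0.56 ± 0.10 (adjusted p = 0.0068), Tet1, a DNA demethylase, by 0.82 ± 0.14 and Rtkn2 by 1.09 ± 0.22. Oxidative phosphorylation genes were above 0 in 61 of 70 cases, none past over all genes and 17 higher over the list alone (median 0.09, adjusted p = 5e-10; adjusted p = 0.51 with an estimated correlation). Tendon and cartilage markers were all below 0, none past over all genes and 7 of 13 lower over the list alone (median -0.71, adjusted p = 1.1e-08; adjusted p = 0.51 with an estimated correlation), with a median of -0.36 without the lymph node arrays. The count was 10, 16 and 4 without 2-week replicates 1, 4 and 6 and 13, 10, 16, 11 and 10 without 24-week replicates 1, 2, 4, 5 and 6; it was 335 without the lymph node arrays, with 24 of the 27 among them.

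Whether the response to smoke changed with time was tested as an interaction. From 2 to 24 weeks it differed in 4 genes. Nr1d1 differed from air by -0.06 ± 0.16 at 2 weeks and by -1.13 ± 0.16 at 24 weeks (SE, n = 6 each), a change of -1.07 ± 0.22. Kcnf1 went from 0.59 ± 0.22 to -0.88 ± 0.22, 4930553P18Rik from 0.44 ± 0.12 to -0.44 ± 0.12, and Fam227b from -0.33 ± 0.08 to 0.25 ± 0.08. All 4 had an adjusted p that lies below 0.05 and rounds to it. The count was 0 without any one of 2-week air replicates 1, 2, 3 and 6, 2-week smoke replicates 1, 2, 3 and 5, 24-week air replicates 1, 3, 4, 5 and 6 and 24-week smoke replicate 6. It was 1 and 11 without 2-week air replicates 4 and 5, and 22, 2, 7, 7 and 9 without 24-week smoke replicates 1, 2, 3, 4 and 5. It was 18 without the lymph node arrays, with 2 of the 4 among them, and Kcnf1 (-0.97) and Fam227b (0.52) no longer passed. From 2 to 12 weeks limma called 0 genes, with 251 at an unadjusted p under 0.05, and from 12 to 24 weeks 0, with 557. Chance gives 618 on average, but genes that shift together let such numbers lie far from it. They do not show that the response stayed the same, and no other tool was run gene by gene. The Cyp1a1 difference at 12 weeks is thus not shown to differ from that at 2 or 24 weeks. The 12 to 24 week count was 1 without 12-week air replicate 5, 12-week smoke replicate 3 or 24-week smoke replicate 4.

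A score of the 12-week smoke response asked whether it was present after cessation. It averaged 100 genes of lowest p at 12 weeks, 28 higher and 72 lower, chosen on mice outside the test, none of them lymphocyte markers. Only Cyp1a1 among them had passed at 12 weeks, and the clock genes Nr1d1 and Clock and the liver gene Alb were members. The score thus rests mostly on genes with no established response and cannot decide whether a response to smoke persisted. The score was -0.06 ± 0.04 in cessation FA, 0.00 ± 0.10 in RA, 0.12 ± 0.17 in 24-week smoke and -0.05 ± 0.09 in 24-week air (SD, n = 6 each). Cessation differed from air by -0.01 in FA (two-sided exact permutation p = 0.87, adjusted p = 0.87 over 5 tests) and 0.05 in RA (exact p = 0.33, adjusted p = 0.41). Smoke at 24 weeks differed from air by 0.17 (exact p = 0.037, adjusted p = 0.092), from FA by 0.18 (exact p = 0.0065, adjusted p = 0.032) and from RA by 0.12 (exact p = 0.16, adjusted p = 0.27). With the lymph node arrays left out, the 100 genes were chosen anew from that fit, so both the genes and the mice changed. Smoke then differed from FA by 0.01 (exact p = 0.75) and from air by 0.07 (exact p = 0.036, adjusted p = 0.09). RA then differed from air by 0.08 (exact p = 0.036, adjusted p = 0.09) and FA by 0.06 (exact p = 0.13). Smoke replicate 6 had a score of 0.42 and the other 5 smoke mice scores from -0.04 to 0.18. Without it, smoke differed from air by 0.10 (exact p = 0.12, adjusted p = 0.30), from FA by 0.13 (exact p = 0.0065, adjusted p = 0.032) and from RA by 0.06 (exact p = 0.34). The genes were again chosen anew from that fit. With genes chosen at 2 weeks the difference of smoke from air was -0.11 (exact p = 0.019, adjusted p = 0.095).

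Genes called in 2 comparisons with the same 24-week air mice were counted. Of 51 genes lower with 24 weeks of smoke and 142 lower in cessation RA, 8 were shared, and of 9 lower in FA and 142 lower in RA, 7. The number to be had by chance with shared air mice was not computed. No gene called in FA was among those called with 24 weeks of smoke in the same direction. Across genes, which are not independent replicates, r between the differences was 0.18 for 24-week smoke and FA, 0.686 for 24-week smoke and RA and 0.57 for both arms. Simulated data with no difference, the same shared controls and genes drawn independently gave 0.513, 0.503 and 0.497. Shifts shared by many genes were not simulated. With the air mice split between the comparisons r was -0.035, 0.413 and 0.192. Across genes, in comparisons that share no mice, r was 0.649 for 12 and 24 weeks of smoke, -0.544 for 2 and 12 weeks and -0.563 for 2 and 24 weeks, with the lymph node arrays among them.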

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

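Tests chosen only after the result was seen were those of smoke exposure as the cause of the lymphocyte genes, of the lymph node genes that lymphocytes do not express, all 3 on the clock genes, and those of lymph node and liver RNA for Cyp1a1. For the dioxin receptor targets the demand that the result hold without the lymph node arrays, and the test with targets below the filter, were also added then, as were the groupings with arrays left out. In 184 tests, each of 1 measure in 1 group of replicates, 26 found a sample far from the others. Chance gives about 1 in 20, or 9.2, if tests are independent. Many measures here read the same arrays, so 26 cannot be set against 9.2 as an excess. Lymphocyte genes were far above the rest of their group in untreated replicate 1 (10.84, next 7.16), 2-week air replicate 3 (10.23, next 5.85) and 24-week air replicate 6 (10.33, next 6.35). The same arrays, or others with lymph node genes, stood apart in Cyp1b1: untreated replicate 1 at 10.04, 2-week air replicate 3 at 9.37 and cessation FA replicate 4 at 9.37. Mean r with the other arrays, across genes, was low in untreated replicate 1 and 2-week air replicate 3 (0.95 each) and in 24-week smoke replicate 6 (0.83). Cell cycle genes were high in 2-week air replicate 3 (7.78), 12-week air replicate 1 (8.25), 24-week air replicate 6 (7.88) and 24-week smoke replicate 6 (10.23).

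Replicate 6 of 24 weeks of smoke was also lowest of its group in Nqo1 (8.58, next 9.93), in Trim63, a ubiquitin ligase of muscle atrophy (10.06, next 11.27), in Ppargc1a, the co-activator of mitochondrial genes (9.40, next 10.94), and in Vegfa, the vessel growth factor (9.31, next 10.20). Nqo1 was low (9.61) and Hmox1, heme oxygenase, high (8.77) in 12-week smoke replicate 5. Both arrays are among those with lymph node genes, with lymphocyte means of 12.24 and 10.73. So is cessation RA replicate 5 (10.55), named below, while the other arrays named below are not. Mt2 was high in untreated replicate 3 (10.48), 12-week air replicate 1 (10.52) and cessation FA replicate 3 (10.55). Fbxo32 was high in cessation RA replicate 6 (12.61), Vegfa low in cessation RA replicate 5 (9.88), the glucocorticoid target Fkbp5 low in cessation FA replicate 1 (8.76), and fast fibre genes low in 24-week air replicate 3 (13.26). The smoke difference changed between 2 and 24 weeks in Nr1d1 (-1.07), Fam227b (0.58), 4930553P18Rik (-0.88) and Kcnf1 (-1.48), by the interaction test.

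The lymphocyte genes of 12 arrays may come from lymph node tissue in the pieces of muscle taken. Glycam1, a gene of lymph node vessels and milk glands, is not on the lymphocyte list. It averaged 13.14 ± 0.19 (SD, n = 12) in these arrays and 5.88 ± 1.03 (n = 44) in the others. Chst4, Madcam1 and Lyve1, genes of lymph node or lymphatic vessels that lymphocytes do not express, averaged 1.16 higher in these arrays, with Chst4 from 5.47 to 6.49 against 3.71 to 4.79 in the others, while Lyve1 overlapped (8.83 to 10.25 and 7.72 to 9.59). Lymphocytes spread through muscle without a node are argued against by Chst4 and Madcam1, which averaged 1.27 higher (1.08 to 1.48). This test was fixed before its result was seen but after the 12 arrays were known. Chst4, 1.77 higher, carried most of it. Madcam1 was 0.77 higher and overlapped (5.03 to 6.91 and 4.6 to 5.39), and both genes lie near the filter level of 5.71. Smoke as the cause and uneven dissection cannot be told apart, since 9 of 31 mice ever exposed and 3 of 24 never exposed had such arrays, which is too few to decide (Fisher exact p = 0.194, odds ratio 2.81, 0.59 to 18.36). Mouse G8, with lymphocyte means of 5.39 and 10.93 in its 2 arrays, varied between arrays of the same label.

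The clock gene differences may come from different times of day of tissue collection, which the sources used here do not give. Across 20 clock genes, which are not independent replicates, r between cessation RA minus 24 weeks of air and untreated minus 2 weeks of air was 0.872 (0.443 over all genes). The second of these differences involves no smoke. It does hold the sham exposure, which untreated mice did not have, so r cannot part sham exposure from collection time. Smoke as the only cause of clock gene differences in these data is argued against by 4 clock genes that differed between untreated mice and 2 weeks of sham air. These genes do not tell whether smoke acted in the other groups. For cessation FA r was 0.749 and for 24 weeks of smoke 0.283. In these groups and in RA, smoke or its withdrawal and collection time cannot be told apart, because each group was a single set of mice. The interaction of Nr1d1 belongs to the same open question, and a different kind of air in RA, whose label the air groups do not share, was not tested.

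Cyp1a1 at 12 weeks of smoke, at adjusted p = 0.51 with the 12-week groups fitted alone, may reflect activation of the dioxin receptor AHR in muscle, a hypothesis. Lymph node tissue is argued against by a difference of 1.55 without those arrays and lung RNA by 0.01 over 9 lung genes (-0.15 to 0.17). The 11 liver genes averaged 0.40 higher with smoke (0.01 to 0.92, exact permutation p = 0.043) and Alb was 6.89 against 5.47, but liver RNA as the whole cause is argued against by 1.62 ± 0.25 (SE) for Cyp1a1 with these genes as a covariate. Cyp1b1, Tiparp and Nqo1, the other AHR targets above the filter, averaged 0.41 higher (0.08 to 0.78, exact permutation p = 0.017). This list was not among those fixed before the data were examined. The mean was carried by Cyp1b1 (7.51 against 6.09), with Tiparp (10.17 against 10.23) and Nqo1 (10.16 against 10.28) lower. Without the lymph node arrays these genes averaged 0.20 higher (exact permutation p = 0.10). With Ahrr (4.89 against 4.27), Aldh3a1 (5.64 against 5.27) and Cyp1a2 (4.73 against 4.82), all below the filter, the mean was 0.36 (exact p = 0.0052) and 0.18 without those arrays (exact p = 0.013), but 3 dim genes do not decide it, and receptor activation cannot be told apart from another route to Cyp1a1.

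In 100 groupings of the same mice, the true one among them and the others mixed, the rank of the true count was taken. It was called low where under 5% of groupings called as many genes. With 14 comparisons and no adjustment over them, a low rank does not exclude chance. The rank was low for 12 weeks of smoke (3 of 100 called as many, 1 gene in truth, highest other 1). It was also low for the mean of 3 times (1 of 100, 4 genes, highest other 0) and cessation FA (1 of 100, 10 genes, highest other 1). The same held for cessation RA (3 of 100, 217 genes, highest other 772) and RA against FA (1 of 100, 3 genes, highest other 2). Low ranks were also found for 2 weeks of air against untreated (1 of 100, 64 genes, highest other 5) and 24 against 2 weeks of air (1 of 100, 27 genes, highest other 1). The 24 against 2 week interaction had one too (2 of 100, 4 genes, highest other 419). The rank was not low for 24 weeks of smoke against air (14 of 100, 58 genes, highest other 4422). Nor was it against cessation FA (6 of 100, 438 genes, highest other 2871) or against RA (16 of 100, 289 genes, highest other 4232). Where 0 genes were called, at 2 weeks of smoke and in the 12 against 2 and 24 against 12 week interactions, 100 of 100 called as many, with highest counts of 0, 1 and 3443. Mixed groupings that call several times the real count point to a structure of the samples other than their groups. Without the 12 lymph node arrays, on fewer mice, 6 of 56 groupings called as many for 24 weeks of smoke against air (45 genes, highest other 184). Against FA 1 of 56 did (234 genes), a low rank. Against RA there were too few mice for a low rank (10 groupings, 405 genes, highest other 2). Without smoke replicate 6 the rank was 17 of 100 against air (4 genes, highest other 734) and 1 of 100 against FA (126 genes, highest other 60). It was 5 of 100 against RA (250 genes, highest other 1457), so that it was low against FA alone. For the 24 against 2 week interaction 3 of 100 called as many without the lymph node arrays (18 genes, highest other 53). With smoke replicate 6 alone left out the count was 0 and 100 of 100 did. Replicate 6 is also 1 of the lymph node arrays, so the rank was low in 1 fit without it and not in the other. The 24 against 12 week interaction gave 9 of 100 (2 genes, highest other 870) without the lymph node arrays and 0 genes without replicate 6 (highest other 10). Cessation RA against air still gave 693 without the lymph node arrays (2 of 56, 490 genes), so these arrays are not shown to be the whole of that structure.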

How the results depend on the processing

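Fits chosen only after the data were seen were those without the 12 lymph node arrays, with the lymphocyte mean as a covariate, and without the outlying array of 24 weeks of smoke. Of 5751 values of named genes under alternatives 5396 kept their side of the threshold, 276 lost the call and 79 gained it. Of those called before or after, 0 turned direction, and 65 values never called changed sign. The 5751 include genes not called in the main fit, such as all those at 2 weeks of smoke. These kept their side by staying uncalled, so 5396 does not measure how stable the calls are. No paired analysis was possible because replicate numbers only follow the order of the samples and the labels name no shared mouse, litter or day. The 100 lowest-p genes are already the score's genes, since fewer than 20 genes passed, so that alternative was not run apart. Trend with robust moderation and a pseudocount of 64 moved no count by over 1.5 times. Genes near background are limited by the signal of the arrays. Unless a reason is given, the cause of a move was not tested.

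Counts below are for 24 weeks of smoke against air at 58, the mean of 3 times at 4, cessation FA at 10, RA at 217, 24 weeks of smoke against FA at 438 and against RA at 289, RA against FA at 3, 2 weeks of air against untreated at 64, 24 against 2 weeks of air at 27 and the 24 against 2 week interaction at 4. The interaction went to 0 with no filter, the 60th percentile, all probe sets, the mean of probe sets, a pseudocount of 1, the title number, G8 arrays apart or its main-run array alone, arrays outside the main run left out, the lymphocyte covariate and the compared groups alone, and to 1 with quantile normalization. With no filter 24 weeks of smoke gave 29, FA 0 and smoke against FA 284. The 60th percentile gave 140 for 24 weeks of smoke and 1 for RA against FA. All probe sets gave 1 at 2 weeks and 2 at 12 weeks of smoke, 8 for the mean, 3 in FA and 732 for smoke against FA. The mean of probe sets gave 17 in FA and 5 for RA against FA, as did a pseudocount of 1 there (5). The compared groups alone gave 0 at 12 and 24 weeks of smoke and in FA. They gave 6 for smoke against FA, 4 against RA and 9 for the air times. That fit had fewer degrees of freedom and took its spread from those groups only, and which of these moved the counts was not tested. The main fit takes 1 spread per gene, although spreads differed, as for Nr1d1 (SD 0.58 with 24 weeks of smoke, 0.2 with air). Array weights gave 2 at 12 and 568 at 24 weeks, 61 for the mean, 45 in FA, 905 in RA, 602 for smoke against RA, 32 for RA against FA, 663 and 981 for the air comparisons, and 736 and 10 for the 24 against 2 and 24 against 12 week interactions. The title number gave 13 at 24 weeks, 6 for RA against FA and 13 for the air times. Arrays outside the main run left out gave 1299 for smoke against FA. An adjusted p under 0.1 gave 809, 15, 23, 373, 1515, 502, 6, about 1.0e2, 49 and 14 in the order above.

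Without the 12 lymph node arrays, on fewer mice, the counts were 19 for the mean, 29 in FA, 490 in RA, 234 for smoke against FA, 236 and 335 for the air comparisons, and 18 and 2 for the 24 against 2 and 24 against 12 week interactions. The lymphocyte covariate gave 24 at 24 weeks, 11 for the mean, 35 in FA, 539 in RA, 250 and 771 for smoke against FA and RA, 9 for RA against FA, and 148 and 64 for the air comparisons. Without the outlying array, which lowers the pooled spread, FA gave 33, RA 520, RA against FA 7 and the air comparisons 146 and 117.

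Of 155 list calls with camera over all comparisons, 0 were left with an estimated correlation and 4 with fry. With an estimated correlation, 1 list passed without the lymph node arrays, muscle atrophy genes lower after 2 weeks of air than in untreated mice (adjusted p = 0.012). Without the outlying array that list (adjusted p = 0.0037), fatty acid oxidation in the same comparison (0.018) and the clock list in RA against air (0.007) passed. Calls of the score are here by the unadjusted exact p. Its genes were chosen anew with the 60th percentile, with quantile normalization and in fits with arrays left out. The score turned with genes chosen at 2 weeks (24 weeks of smoke against air -0.11, against FA -0.09). It lost the call with genes at an adjusted p under 0.1, which leaves Cyp1a1 alone (0.37 and 0.33), against air with quantile normalization (0.15) and against FA without the lymph node arrays (0.01), where RA against air gained it (0.08). It also lost the call against air without the outlying array (0.10). By the adjusted p only smoke against FA had passed (0.032). It kept the call with the 60th percentile (0.022) and without the outlying array (0.032), and lost it with quantile normalization (0.095), genes chosen at 2 weeks (0.22), Cyp1a1 alone (0.62) and without the lymph node arrays (0.94).

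Leaving out 1 replicate at a time gave 0 to 0 at 2 weeks of smoke, 1 to 1 at 12 weeks, 4 to 547 at 24 weeks, 4 to 10 for the mean, 0 to 10 in FA, and about 1.2e2 to 286 in RA. It gave 126 to 1625 for smoke against FA, 142 to 481 against RA, 2 to 4 for RA against FA, 35 to 70 and 4 to 35 for the air comparisons, and 0 to 0, 0 to 22 and 0 to 1 for the 12 against 2, 24 against 2 and 24 against 12 week interactions.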

Other observations

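The list tests given next had been fixed before the data were seen, and none passed with an estimated correlation. From 2 to 24 weeks of air all 16 slow fibre genes lay above 0, none past (median 0.31, adjusted p = 0.00026; adjusted p = 0.61 with an estimated correlation), and so did all 21 macrophage markers (median 0.54, adjusted p = 0.00026; adjusted p = 0.83 with an estimated correlation). Fatty acid oxidation genes lay above 0 in 29 of 30 cases, with 1 past, Pdk4, and 5 over the list alone (median 0.20, adjusted p = 4.5e-08; adjusted p = 0.51 with an estimated correlation). With 12 weeks of smoke, 33 extracellular matrix genes had a median of -0.10 and none passed (adjusted p = 0.0053; adjusted p = 0.87 with an estimated correlation), among them Loxl1, a cross-linking enzyme of elastin, at -0.27 and the collagen chain Col5a1 at -0.31. With 2 weeks of smoke, 7 nerve and Schwann cell markers all lay below 0, none past (median -0.32, adjusted p = 0.014; adjusted p = 0.71 with an estimated correlation), and 24 of 31 proteasome subunits lay above 0, none past (adjusted p = 0.0011; adjusted p = 0.71 with an estimated correlation).

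The 2 arrays of mouse G8 had an r of 0.902 across genes, the lowest of the 28 pairs of arrays in its group, whose median was 0.985. Their Cyp1a1 levels were 9.43 and 9.19.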
